A study of Mus musculus with 8 samples.

How the data were processed

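The material was bone marrow flushed from the femurs of 10-week-old C57BL/6 mice and kept for 5 days in Iscove's medium with 10% fetal calf serum and IL-7, a cytokine under which B cell precursors grow out. Total RNA of 8 such cultures, 2 in each of 4 groups, was hybridised to 8 one-colour Agilent 4x44K mouse arrays as Cy3-labelled cRNA made with an oligo-dT primer, per the labels' protocols. The groups were Bob1 knockout mice, the wild-type mice kept with them, miR-146a knockout mice, and a separate set of wild-type mice, called BL6 wild-type here and labelled C57BL/6Ncrl. In each group, replicate A came from female and replicate B from male mice. The labels call the arrays of a group biological duplicates without saying how many mice went into a culture, so the p-values measure the spread between these cultures. With 2 arrays in a group, their number limits the precision of every value.

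Per the file headers, the spots were quantified with Feature Extraction 10.5.1.1, and the intensity used here is its processed signal, from which the background had been subtracted and a spatial trend within the array removed, with no normalization between arrays. The scanner files also hold a flag per spot (1 or 0) for a signal well above background, for saturation and for outliers, as Feature Extraction deposited them. The authors' deposited value table holds log2 values of the same arrays, and limma is named as a tool in the submitters' processing notes without a version. Its columns have medians of 9.587 to 9.589 and range from 4.49 to 19.25. Each column correlated best in rank with the scanner signal of its own array (0.971 to 0.984, against at most 0.965 for another array). The values lie on a log scale to which a constant seems to have been added before the logarithm, since low signals are compressed near 9.5, and the exact normalization is not given in the sources used here. This table served only as an alternative, and 93 of its 41267 probes were controls and were left out.

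From the scanner files, control spots and spots with an outlier flag (71 to 156 per array) were left out, and no spot was saturated. The log2 processed signal of each array was taken relative to that array's 75th percentile, and spots of a probe were averaged. These relative log2 values are the levels given in the text, and a level of 0 is the 75th percentile of that array. The 75th percentile lay between 493 and 782 intensity units, and between 60.5% and 66.1% of the probes of an array were well above background. Of 41174 probes, 27584 were named through their transcript accession in a RefSeq gene table of assembly GRCm38.p6, 7197 kept the name in the scanner file and 6393 had no symbol. The probe coordinates come from the scanner files and are those of mm9. The gene table was used only for names and for which genes neighbour each other.

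A probe was tested if it was well above background on both arrays of at least 1 group, which 26528 probes were. A gene with several such probes was represented by the probe with the highest mean level over the 8 arrays, and probes without a symbol were tested on their own, which gave 17493 features (14577 with a symbol and 2916 without). All 8 arrays entered a limma fit with 4 group means, so that the groups shared an estimate of the spread with 4 residual degrees of freedom. The contrasts were Bob1 knockout against Bob1 wild-type, miR-146a knockout against BL6 wild-type, Bob1 wild-type against BL6 wild-type, and the Bob1 effect minus the miR-146a effect. P-values were moderated by limma's empirical Bayes step and adjusted by the Benjamini-Hochberg method over all features of a contrast, with a threshold of 0.05 and no minimum fold. SE stands for limma's moderated standard error of a log2 fold change. Rose, fell and called are used of features past that threshold. Counts at an unadjusted p under 0.05 are given beside the calls. Without any difference, a share of 0.05 of the tested features is expected among them. A gene that was not well above background on either array of the dimmer group has only a bound for its fold change. It is given as at least N-fold, from the mean of the brighter group against, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal of any probe well above background. The tools were R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8).

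Before the data were examined, the groups, the tests, the planned processing alternatives, the rule for naming genes and the gene lists were fixed. Of 24 lists, 21 had at least 3 tested members. They were early B cell genes, pre-B cell receptor signalling, mature B cell genes, immunoglobulin genes, genes reported as octamer or Bob1 dependent, reported miR-146a targets, NF-kB response, interferon response, IL-7 and STAT5 response, cell cycle, p53 and apoptosis, unfolded protein stress and immediate early genes. The remaining lists held markers of myeloid, erythroid, T and NK, dendritic, mast and basophil, megakaryocyte, stromal and endothelial, and stem and progenitor cells. The 3 small lists served as checks and held the disrupted genes, sex-linked genes and Nnt, a gene with an inherited deletion in some C57BL/6 substrains. The 2 lists of reported targets came from the literature in general, not from these arrays. Lists were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, each adjusted over the 21 lists. Camera compares a list with all other features, while fry asks only whether its members move one way on balance. Several lists share members. Of the tested members, another list also holds 8 of 13 octamer genes, 6 of 26 miR-146a targets, 5 of 32 mature B cell genes, 5 of 30 NF-kB genes, 5 of 12 stem cell markers and at most 3 of any other list. Of the members with a probe on the array, 10 of 15 mast, 12 of 16 erythroid, 14 of 18 stromal, 14 of 16 dendritic, 23 of 24 T and NK, 12 of 13 stem cell, 13 of 15 octamer and 26 of 29 miR-146a target genes passed the filter and were tested, and all of them in the other tested lists. A list of immunoglobulin features by their description in the scanner file was added after the data were seen, because most of these probes have no symbol.

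The genes named in the text are Pou2af1 and any probe for miR-146a, the 10 largest rises and the 10 largest falls of each knockout comparison among called genes whose knockout arrays both lay on the same side of both wild-type arrays, and 5 each way in the other contrasts. Genes were ranked by fitted log2 fold change, also those that have only a bound. Clone-like, predicted-gene and RIKEN symbols were counted without being named. Up to 4 called members of each list were added by size, or, where none was called, the 2 with the smallest p as values. Sex-linked genes, Nnt and genes called in both knockout comparisons were also named, and where fewer than 5 genes passed a comparison, also the 5 with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

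The 8 arrays lay on 2 slides of 4 arrays, with a scan time each. Both Bob1 wild-type arrays were on slide 1 and both Bob1 knockout arrays on slide 2, while BL6 wild-type and miR-146a knockout had 1 array on each slide. Slide and scan therefore coincide with genotype in the Bob1 comparison, and a slide effect can be estimated there only from the other 4 arrays, with the slide as a block in the fit. For the miR-146a comparison, values within each slide are given as well. Slide 1 held BL6 wild-type replicate A (female) and miR-146a knockout replicate B (male). Slide 2 held BL6 wild-type replicate B (male) and miR-146a knockout replicate A (female). A value within a slide is therefore also a difference between the sexes and between single arrays.

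The alternatives were quantile normalization, normexp background correction of the mean signal (offset 50) with either normalization, no filter on dim probes, a filter that asks for all 8 arrays, every probe on its own or the mean over probes of a gene, the slide as a block, the replicate block alone and with the slide, only the arrays of a comparison, all 4 wild-type arrays as control, a trended and robust prior, other thresholds, the deposited table, and leaving out each array in turn. Normexp without spots dimmer than their local background was added after the data were seen. Planned searches for miR-146a seed matches in transcripts and for octamer motifs in promoters need a genome sequence and were not run, so nothing here says which of the changed genes carry such sites.

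The fit was tested on simulated data drawn from the measured means and spreads of 17445 genes, with 200 genes changed, in 20 runs. For the Bob1 comparison it found 1.1%, 36.5% and 79.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 6.2% false calls. With the slide as a block the shares were 0.1%, 0.1% and 12.2%. For the miR-146a comparison they were 0.9%, 34.5% and 75.3%, with 4.5% false calls. A list of 30 genes shifted by 0.5 was called in 20 of 20 runs, and an unshifted list in 0 of 20. The simulation contains no slide effect and says nothing about one. Its genes were also drawn independently of each other. It therefore says nothing about false calls of lists whose members vary together, as those of several lists did here.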

Results

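The arrays measured transcript levels in bone marrow cultures grown with IL-7 for 5 days. They compare whole cultures from mice that lack the transcriptional coactivator Bob1, or the microRNA miR-146a, with wild-type cultures. There were 2 biological replicates in each of 4 groups, Bob1 wild-type, Bob1 knockout, BL6 wild-type and miR-146a knockout. Between 60.5% and 66.1% of the probes of an array were well above background, and the 75th percentile of the signal ran from 493 to 782 units. The Bob1 knockout arrays were the dimmest (493 and 621 units) and held the lowest shares (60.5% and 63.1%). Replicates of a group correlated with r between 0.988 and 0.993 over the tested features, across genes, and the replicates of a group shared 0 identical values. The Bob1 knockout arrays correlated with the other 6 at 0.970 to 0.979, while those 6 correlated with each other at 0.988 to 0.994. The principal component that separated the Bob1 knockout arrays from the rest carried 52% of the variance. Xist lay between 4.48 and 5.02 on the 4 female arrays and between -6.96 and -5.98 on the 4 male arrays. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background only on the 4 male arrays, as labelled.

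Pou2af1, the gene that encodes Bob1, was checked in every group. Its level was 2.77 ± 0.08 in Bob1 knockout cultures and 6.48 ± 0.11 in Bob1 wild-type cultures (SD, n = 2 each), a 13.1-fold fall (log2 fold change -3.71, SE 0.16, limma adjusted p = 0.000242). The log2 fold change was -3.97 with the slide as a block (adjusted p = 0.00514). The 6 arrays of the other groups lay between 6.40 and 6.71. The probe lies on chromosome 9 at 51048108 to 51048167 (mm9). Whether this position belongs to the part deleted in the knockout mice is not given in the sources used here, so the fall matches the labels without showing the deletion itself. The array holds no probe for miR-146a, and the labels of the miR-146a knockout arrays were not checked by their target. In that comparison Pou2af1 had a log2 fold change of -0.04 (adjusted p = 1), a value near 0 whose sign turned under some settings, such as 0.02 with quantile normalization.

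**Figure D1:**
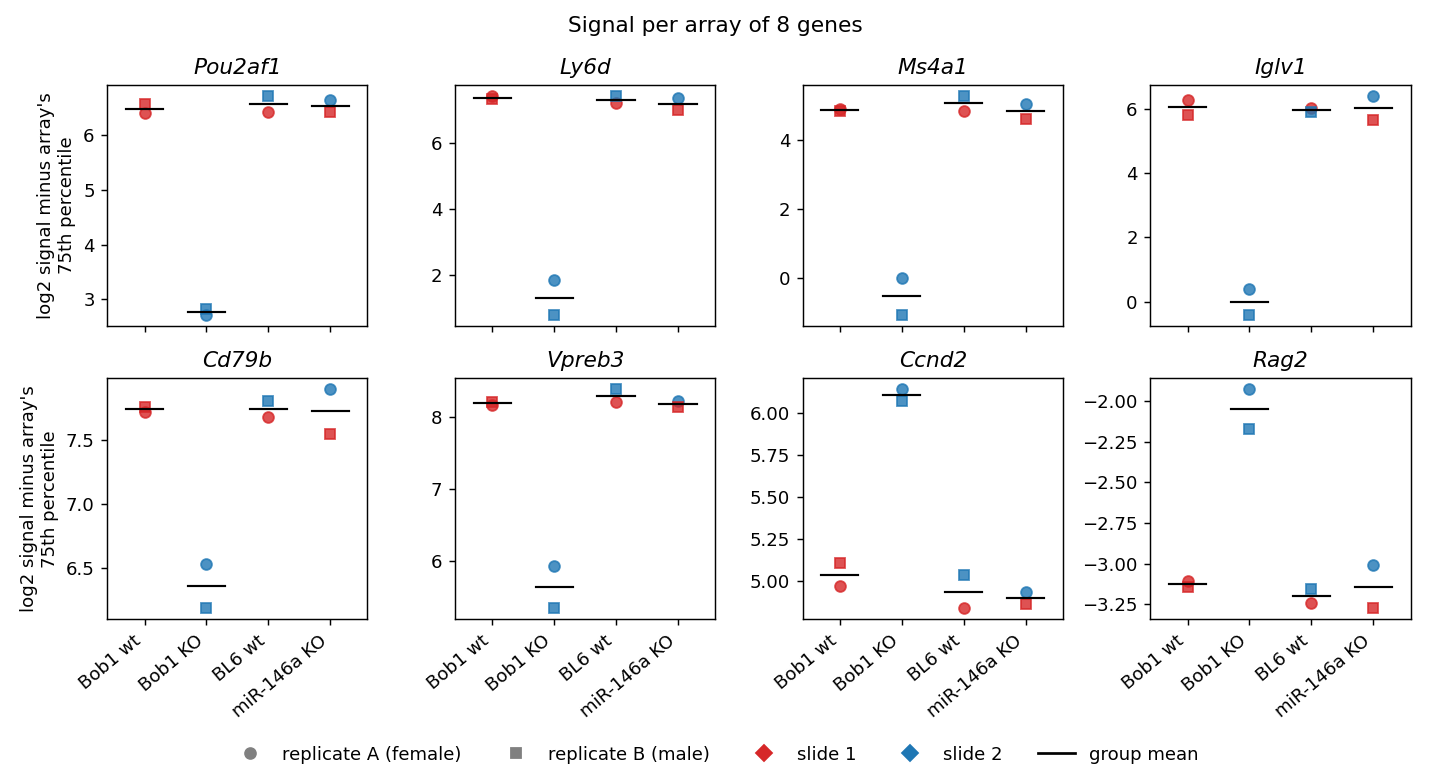
Levels of 8 genes on each array (log2 signal minus the array's 75th percentile), with circles for replicate A (female), squares for replicate B (male), red for slide 1, blue for slide 2 and a bar for the group mean. Pou2af1, Ly6d, Ms4a1, Iglv1, Cd79b and Vpreb3 lie lower, and Ccnd2 and Rag2 higher, on both Bob1 knockout arrays than on both Bob1 wild-type arrays.

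The 10 largest falls of named genes in Bob1 knockout cultures included transcripts of surface proteins and of light chain segments. Ly6d, a lymphocyte surface antigen, fell 66.4-fold, from 7.37 ± 0.08 to 1.32 ± 0.75 (SD, n = 2 each; log2 fold change -6.05, SE 0.34, limma adjusted p = 0.000508). Ms4a1, which encodes the B cell antigen CD20, fell 42.3-fold, from 4.86 ± 0.03 to -0.54 ± 0.76 (adjusted p = 0.000971). Iglv1, a lambda light chain variable segment, fell 66.0-fold, from 6.03 ± 0.34 to -0.01 ± 0.58 (adjusted p = 0.000612), and its 5 probes moved by -4.31 to -6.08. Among the largest falls were also Prm1, a sperm protamine gene (61.9-fold, adjusted p = 0.000373, with its 3 probes apart at -1.89, -5.95 and -6.55), the kappa segment Igkv6-14 (21.5-fold, adjusted p = 0.000432), the transcription factor Egr3 (at least 6.95-fold, adjusted p = 0.000759) and the transporter gene Slc47a1 (at least 5.44-fold, adjusted p = 0.000305). The ranks of Egr3 and Slc47a1 rest on fitted folds, as their bounds lie below measured falls such as that of Jchain (13.6-fold). The mm9 probe positions of the leading genes were 74592551 to 74592610 on chromosome 15 for Ly6d, 11325367 to 11325426 on chromosome 19 for Ms4a1 and 19061826 to 19061885 on chromosome 16 for Iglv1. The remaining genes of the 10 were Fcmr, the Fc receptor for IgM (23.2-fold, adjusted p = 0.0104), Igkv9-120 (at least 16.7-fold, adjusted p = 0.017) and H2-DMb2, an MHC class II loading chaperone (fitted 27.5-fold, adjusted p = 0.0358, of uncertain size with only 1 of the 2 knockout arrays well above background). These 3 calls were lost without Bob1 wild-type replicate A, with adjusted p of 0.066, 0.0927 and 0.152. Igkv9-120 was also lost without Bob1 wild-type replicate B (0.0601), and H2-DMb2 without Bob1 wild-type replicate B (0.0944), either BL6 wild-type array (0.0614) or either miR-146a knockout array (0.0702).

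By fitted folds, the largest rises in Bob1 knockout cultures were mostly of genes that were not well above background in the wild-type cultures. They were the ankyrin repeat gene Asb10 (at least 21.2-fold, limma adjusted p = 0.000107), the chemokine gene Ccl21a (at least 6.82-fold, adjusted p = 7.65e-05), the matrix gene Edil3 (at least 5.28-fold, adjusted p = 0.000121) and the chemokine receptor gene Ccr10 (at least 4.53-fold, adjusted p = 0.0104). Ghrh, which encodes growth hormone releasing hormone, was measured on both sides and rose 10.8-fold (log2 fold change 3.43, SE 0.16, adjusted p = 0.000305). Apart from Asb10, the genes of this paragraph with only a bound have bounds below that fold, so their ranks are not established. Pdcd1, which encodes the inhibitory receptor PD-1, rose 10.4-fold (3.38, SE 0.57, adjusted p = 0.025), a call lost without Bob1 wild-type replicate A (0.0816) or B (0.0888) and without Bob1 knockout replicate A (0.0938) or B (0.0799). Capza3, ccdc198, Tas2r105 and Uroc1 rose at least 7.32-, 5.64-, 3.06- and 4.14-fold, with adjusted p of 0.0104 to 0.0221. Of these, Capza3, Tas2r105 and Uroc1 were lost without Bob1 wild-type replicate A (0.0629, 0.0666 and 0.0965) or B (0.0519, 0.0538 and 0.0821), and ccdc198 without Bob1 knockout replicate A (0.0542).

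In all, 1198 of 17493 features were called between the Bob1 genotypes, of which 622 rose and 576 fell, and 622 changed at least 2-fold with unmeasured features at their bound (239 up, 383 down; 656 by fitted folds). At an unadjusted p under 0.05 there were 5057. The median log2 fold change over all features was 0.12, and other scalings moved it to between -0.03 (normexp) and 0.18 (normexp without spots under their background), so shifts of gene groups are best read against it. Of the called features 341 had no symbol, and 130 were not well above background in one of the genotypes (33 that rose and 97 that fell). Of 42 features that fell at least 16-fold with unmeasured features at their bound, 28 were described as immunoglobulin sequences. The split of rises and falls was 2710 to 847 with normexp without spots under their background and 623 to 366 with the deposited table.

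The slides limit this comparison, because both wild-type arrays lay on slide 1 and both knockout arrays on slide 2, so no value within a slide exists. With the slide as a block, estimated from the other 4 arrays, 122 features were called (22 up, 100 down), of which 119 were among the 1198, and all 1198 kept their direction. The median absolute log2 fold change of the 1198 went from 1.05 to 1.01, while their median SE rose from 0.17 to 0.24, since the block takes the slide estimate from 4 arrays. In the blocked fit Ly6d had -6.34 (adjusted p = 0.0189), Ms4a1 -5.85 (0.0196), Iglv1 -6.36 (0.0191), Prm1 -6.30 (0.0109), Igkv6-14 -4.70 (0.0132) and Ghrh 3.20 (0.0109). Egr3 (0.0308), Slc47a1 (0.0109), Asb10 (0.00685), Ccl21a (0.00514) and Edil3 (0.00798), which have only a bound, kept their call and direction in it. The calls of Fcmr, Igkv9-120, H2-DMb2, Ccr10, Pdcd1, Capza3, ccdc198, Tas2r105 and Uroc1 were lost in it (adjusted p from 0.0909 to 0.324). Limma called 0 features for the slide itself, with 438 at p under 0.05, less than a share of 0.05 of those tested. The number of calls also depended on single arrays and was 346 without Bob1 wild-type replicate A, 467 without replicate B, 534 and 590 without Bob1 knockout replicate A and B, and 632 without either miR-146a knockout array. With the replicate letter, which coincides with sex, as a block it was 1867. Of 65 called genes named for this comparison, 24 kept the call without each array in turn.

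Immunoglobulin genes fell as a group. Of 9 tested members of the fixed list 7 fell and 0 rose by limma (0 at p under 0.05), with 8 falls adjusted over the list alone. The list median was -2.42 (camera adjusted p = 5.07e-10, and adjusted p = 0.168 with an estimated correlation), and with the slide as a block it was -2.13 (8.05e-12). Jchain, which joins IgM and IgA into polymers, fell 13.6-fold (log2 fold change -3.77, SE 0.26, adjusted p = 0.00105, and 0.032 with the block). Ighm, the mu heavy chain gene, chosen after its values were seen, was at 8.63 ± 0.02 against 8.79 ± 0.03 (SD, n = 2 each; -0.17, SE 0.14, adjusted p = 0.435). By the file's descriptions, a list chosen after seeing the data, 107 of 126 immunoglobulin features fell and 0 rose (1 higher at p under 0.05), with a median of -2.47, or -1.89 with unmeasured features at their bound, and -2.39 with the slide as a block. The falls were 47 of 55 kappa features (median -3.71, or -3.41 with unmeasured features at their bound), 51 of 61 heavy chain features (-1.02, or -0.99), 6 of 7 lambda features (-4.16, with or without bounds) and 3 of 3 light chain features of unnamed type (-3.62, or -3.10). The difference between these classes was not tested. Markers of myeloid, T and NK, dendritic, mast and megakaryocyte cells had a median of -0.88 (78 markers), near that of the heavy chain features. These were markers whose Bob1 wild-type level was high enough to show a log2 fold change of -1.78 before reaching the lowest detected signal. Erythroid, stromal and stem cell lists were not part of this set.

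Mature B cell genes shifted downward as well. Of 32 members 18 fell and 1 rose, with 25 falls and 2 rises adjusted over the list alone, and the median was -1.50 (camera adjusted p = 4.97e-16, and adjusted p = 0.168 with an estimated correlation; -1.37 and 2.4e-19 with the slide as a block). Besides Ms4a1 and H2-DMb2, the costimulatory receptor gene Cd40 fell 5.26-fold (adjusted p = 0.000701, and 0.0285 with the block) and the activation antigen gene Cd83 fell 5.70-fold (adjusted p = 0.0091). The gene that rose, chosen after its value was seen, was the transcription factor Irf4 (2.14-fold, adjusted p = 0.0119). Cd83 lost its call without Bob1 wild-type replicate A (0.0518), and Irf4 without Bob1 wild-type replicate A (0.066) or B (0.0598) or Bob1 knockout replicate A (0.0572). With the block Cd83 (0.137) and Irf4 (0.188) lost their calls. H2-DMb2 is open to single arrays as given above, for example 0.152 without Bob1 wild-type replicate A.

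Early B cell genes split. Of 28 members 4 rose and 3 fell, with 5 rises and 3 falls adjusted over the list alone, and camera made no call (adjusted p = 0.971), its direction being down while the median was 0.11 and the mean -0.02. The median was -0.05 with the slide as a block (adjusted p = 0.373). The falls were Vpreb3 (5.90-fold, from 8.19 ± 0.03 to 5.63 ± 0.42, SD, n = 2 each; limma adjusted p = 0.00185), the adhesion receptor gene Cd2 (4.25-fold, adjusted p = 0.00506) and Cd79b, a signalling chain of the antigen receptor (2.61-fold, adjusted p = 0.01). The rises were the recombinase gene Rag2 (2.11-fold, adjusted p = 0.0127) and, chosen after their values were seen, Cd24a (2.11-fold, 0.00531), the IL-7 receptor gene Il7r (1.75-fold, 0.0302) and Bach2 (1.57-fold, 0.0476). In the blocked fit Vpreb3 had -2.69 (0.0407), and Cd79b (-1.62, 0.0748), Cd2 (-2.20, 0.088), Rag2 (0.90, 0.201), Cd24a (0.101), Il7r (0.364) and Bach2 (0.459) were not called. Without Bob1 wild-type replicate A or B, Cd79b had 0.0574 and 0.0529, and Rag2 had 0.0676 and 0.0625, and 0.0562 without Bob1 knockout replicate A. Il7r was lost without any Bob1 array (0.0946 to 0.1) or either BL6 wild-type array (0.0532), and Bach2 without each of the 8 arrays (0.0728 to 0.164).

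Genes downstream of the pre-B and B cell receptor moved both ways. Of 22 members 3 fell and 2 rose, with 5 falls and 2 rises adjusted over the list alone (median -0.09, camera adjusted p = 0.0305, and adjusted p = 0.443 with an estimated correlation; -0.11 and 0.0267 with the slide as a block). The scaffold gene Bank1 fell 12.1-fold (log2 fold change -3.59, SE 0.25, adjusted p = 0.00113) and stayed called with the block (0.0263). Bcar3 fell 2.26-fold (0.03), and the Src family kinase gene Lck and the inhibitory receptor gene Cd22 rose 1.74-fold (0.0286) and 1.53-fold (0.0409), and these calls were lost with the block (0.251, 0.137 and 0.43). Leaving out 1 array removed the call of Bcar3 for each Bob1 array (0.0726 to 0.143), of Lck for each Bob1 or miR-146a knockout array (0.0624 to 0.115) and of Cd22 for each of the 8 arrays (0.0536 to 0.149). The list itself was lost without Bob1 wild-type replicate A (0.0859) or Bob1 knockout replicate B (0.108), and with normexp (0.39).

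Of 13 genes reported as octamer or Bob1 dependent, 3 fell and 1 rose, with 8 falls and 1 rise adjusted over the list alone (median -0.70, camera adjusted p = 9.2e-05, and adjusted p = 0.168 with an estimated correlation; -0.52 and 5.27e-05 with the slide as a block). The falls were Ms4a1, Cd79b and the scavenger receptor gene Cd36 (3.04-fold, adjusted p = 0.024), and the rise was Cd22. Of these only Ms4a1 stayed called with the block (0.239 for Cd36). Cd36 lost its call without Bob1 wild-type replicate A (0.116) or B (0.0742) or either miR-146a knockout array (0.0531). The octamer list shares 8 of its 13 genes with other lists and is no separate line of evidence for those.

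IL-7 and STAT5 response genes also went both ways. Of 20 members 5 rose and 2 fell, also when adjusted over the list alone, with a median of 0.003 and no camera call (direction down, adjusted p = 0.515, although the mean was 0.01; median with the slide as a block -0.003). Mycn rose 2.28-fold (adjusted p = 0.00735), the cyclin gene Ccnd2 2.10-fold (0.00765) and the cytokine signalling inhibitor Socs2 1.98-fold (0.046), while the kinase gene Pim2 fell 2.59-fold (0.00778). The remaining called members, chosen after their values were seen, were Spry1 (1.76-fold up, 0.0229), Spry2 (1.75-fold up, 0.0199) and Socs3 (1.89-fold down, 0.0475). With the slide as a block all 7 calls were lost (Mycn 0.137, Ccnd2 0.138, Socs2 0.458, Pim2 0.11, Spry1 0.237, Spry2 0.232 and Socs3 0.377). Without Bob1 wild-type replicate A, Ccnd2 had 0.0518 and Pim2 0.0534. Socs2 lost its call without each of the 8 arrays (0.052 to 0.195), Spry1 without each Bob1 array (0.0637 to 0.101), Spry2 without Bob1 wild-type replicate A (0.0816) or B (0.0808) or Bob1 knockout replicate B (0.0752), and Socs3 without all but Bob1 knockout replicate A (0.0666 to 0.143).

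Cell cycle genes shifted upward together by a small amount. The median of 32 members was 0.54, against 0.12 for all features (camera adjusted p = 5e-08, and adjusted p = 0.426 with an estimated correlation; 0.50 and 1.92e-07 with the slide as a block), and 22 rose when adjusted over the list alone. Over all features only the mitotic kinase gene Aurkb was called (1.67-fold, limma adjusted p = 0.0391), and leaving out any of the 8 arrays removed that call (0.0565 to 0.163), as did the block (0.406). Birc5 and Ccna2, chosen after their values were seen, had log2 fold changes of 0.66 (adjusted p = 0.0505) and 0.68 (0.0547). Of 19 p53 and apoptosis genes Phlda3 rose (1.72-fold, adjusted p = 0.0358) and 0 fell (1 at p under 0.05), with 2 rises adjusted over the list alone and no camera call (median 0.21, adjusted p = 0.603; 0.19 with the slide as a block). Phlda3 was lost without any Bob1 array (0.0792 to 0.161) or either miR-146a knockout array (0.0713), and with the block (0.268). Of 19 unfolded protein stress genes limma called 0, also over the list alone (3 higher and 1 lower at p under 0.05), with values of 0.44 for Herpud1 (adjusted p = 0.094) and -0.66 for Xbp1 (0.089). Camera gave adjusted p = 0.495 for that list, downward, with a median of 0.01, a mean of -0.04 and a median of -0.01 with the block.

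The NF-kB and immediate early lists shifted downward, with a minority of their genes called. Of 30 NF-kB response genes 8 fell and 0 rose by limma (0 higher at p under 0.05), with 18 falls adjusted over the list alone (median -0.82, camera adjusted p = 1.07e-11, and adjusted p = 0.168 with an estimated correlation; -0.69 and 1.71e-10 with the slide as a block). Bcl3, an atypical inhibitor of NF-kB, fell 3.19-fold (adjusted p = 0.0035, and 0.0497 with the block), and the subunit genes Relb and Nfkb2 fell 2.34-fold (0.00839) and 2.06-fold (0.0178), 2 calls that were lost with the block (0.115 and 0.251). Of 20 immediate early genes 3 fell and 0 rose (2 higher at p under 0.05), with 9 falls and 2 rises adjusted over the list alone (median -0.63, camera adjusted p = 1.95e-06, and adjusted p = 0.309 with an estimated correlation; -0.49 and 7.87e-06 with the block). Besides Egr3 these were Cd69 (3.22-fold, 0.0129) and Egr1 (2.29-fold, 0.0147), which lost their calls with the block (0.203 and 0.166). Relb lost its call without Bob1 wild-type replicate A (0.055), Nfkb2 and Cd69 without Bob1 wild-type replicate A (0.0904 and 0.0747) or B (0.0709 and 0.0568), and Egr1 without Bob1 wild-type replicate A (0.0542) or Bob1 knockout replicate A (0.0667) or B (0.0541).

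Of 38 interferon response genes 3 fell and 0 rose by limma (0 higher at p under 0.05), with 3 falls adjusted over the list alone (median -0.74, camera adjusted p = 5.07e-10, and adjusted p = 0.426 with an estimated correlation; -0.42 and 2.81e-05 with the slide as a block). These were the guanylate binding protein genes Gbp2 (2.84-fold, adjusted p = 0.0426) and Gbp3 (2.11-fold, 0.0123) and the RNA sensor gene Ddx58 (1.79-fold, 0.0347). Of 26 reported miR-146a targets 4 fell and 0 rose (0 higher at p under 0.05), 4 also over the list alone, namely Relb, Irf5 (2.02-fold, 0.00859), Notch2 (1.88-fold, 0.0391) and Egr1 (median -0.27, camera adjusted p = 9.2e-05, and adjusted p = 0.378 with an estimated correlation; -0.21 and 0.000253 with the block). With the block the calls of all these genes were lost (Gbp2 0.302, Gbp3 0.0519, Ddx58 0.344, Relb 0.115, Irf5 0.137, Notch2 0.37 and Egr1 0.166). Gbp3 was lost without any Bob1 array (0.0534 to 0.0718), Gbp2 without all but Bob1 knockout replicate A (0.0649 to 0.172), Ddx58 without any Bob1 array (0.0839 to 0.157) or either miR-146a knockout array (0.0598), Notch2 without each of the 8 arrays (0.0508 to 0.165), and Irf5, Relb and Egr1 without Bob1 wild-type replicate A (0.0542, 0.055 and 0.0542), Egr1 also without Bob1 knockout replicate A (0.0667) or B (0.0541).

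Markers of other bone marrow cells lay lower in Bob1 knockout cultures too, alongside the mature B cell, immunoglobulin, NF-kB and interferon genes. The list medians were -0.93 for myeloid (29 genes), -1.11 for T and NK (23, or -1.06 with bounds), -0.64 for dendritic (14), -0.83 for mast and basophil (10), -0.83 for megakaryocyte (12), -1.11 for stromal and endothelial (14) and -0.88 for stem and progenitor markers (12). Camera called all 7 downward, with adjusted p of 1.11e-09, 0.000231, 0.0248, 0.00483, 0.000227, 0.00231 and 0.0115, and adjusted p = 0.394 to 0.518 with an estimated correlation. With the slide as a block the medians were -0.68 (adjusted p = 1.76e-05), -0.94 (0.00634), -0.45 (0.0876), -0.44 (0.143), -0.69 (0.00343), -0.38 (0.0893) and -0.60 (0.163). Few single markers were called, namely Elane (2.29-fold down, 0.0446), Prf1 (2.08-fold down, 0.029), Irf8 (1.55-fold down, 0.0266) and the endothelial cadherin gene Cdh5 (at least 3.32-fold down, 0.00159), and Mycn, which the stem cell list also holds, rose. Irf8, the only called dendritic marker, is also a member of the mature B cell list, so its fall is not specific to dendritic cells. Adjusted over the list alone, 4 myeloid markers fell (Elane, Csf1r, Cd14 and Prtn3), 1 T and NK marker rose (Zap70) and 1 fell, and 1 dendritic and 1 stromal marker fell, and of these Csf1r, Cd14, Prtn3 and Zap70 were chosen after their values were seen. In the mast and megakaryocyte lists limma called 0 (0 at p under 0.05 for mast and 2 lower for megakaryocyte), with values of -0.85 for Hdc, -0.47 for Kit, -0.87 for Pf4 and -0.99 for Vwf. The brightest myeloid markers in Bob1 wild-type cultures, S100a9 (level 9.10) and Lyz2 (8.46), also chosen after their values were seen, had log2 fold changes of 0.01 and -0.44. Of 12 erythroid markers the carbonic anhydrase gene Car2 rose (2.53-fold, 0.0234) and Ermap fell (at least 1.16-fold, 0.00524, with the sign turned to 0.13 under normexp without spots under their background), 2 rises and 1 fall over the list alone, with no camera call (adjusted p = 0.604, downward with a mean of -0.12 and a median of 0.12, which was -0.49 with the slide as a block).

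Some of these other cell type calls rested on single arrays or ended with the slide as a block. Of the single genes Cdh5 stayed called with the block (0.0478), and Elane (0.442), Prf1 (0.173), Irf8 (0.246), Mycn (0.137), Car2 (0.249) and Ermap (0.101) did not. The mast list was lost without Bob1 wild-type replicate A (0.249), the stem cell list without Bob1 wild-type replicate A (0.121) and in the deposited table (0.0803), the dendritic list without Bob1 wild-type replicate A (0.294) or Bob1 knockout replicate B (0.0943), and the stromal list without Bob1 knockout replicate A (0.0942). Car2 was lost without Bob1 wild-type replicate A (0.0949) or Bob1 knockout replicate A (0.0671) or B (0.0869), Elane without all but Bob1 wild-type replicate B (0.0616 to 0.153), Irf8 without any Bob1 array (0.072 to 0.11) or either miR-146a knockout array (0.0619), and Prf1 without Bob1 wild-type replicate A (0.138) or B (0.0768), Bob1 knockout replicate B (0.0929) or either BL6 wild-type array (0.0526).

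Across the 21 lists, camera called 16 between the Bob1 genotypes, 15 downward and cell cycle upward, and 0 with an estimated correlation (4 at p under 0.05). By fry 7 were called, namely mature B cell, immunoglobulin, octamer, NF-kB, immediate early, cell cycle and miR-146a targets. No list called here changed direction under any of the settings run.

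**Figure D2:**
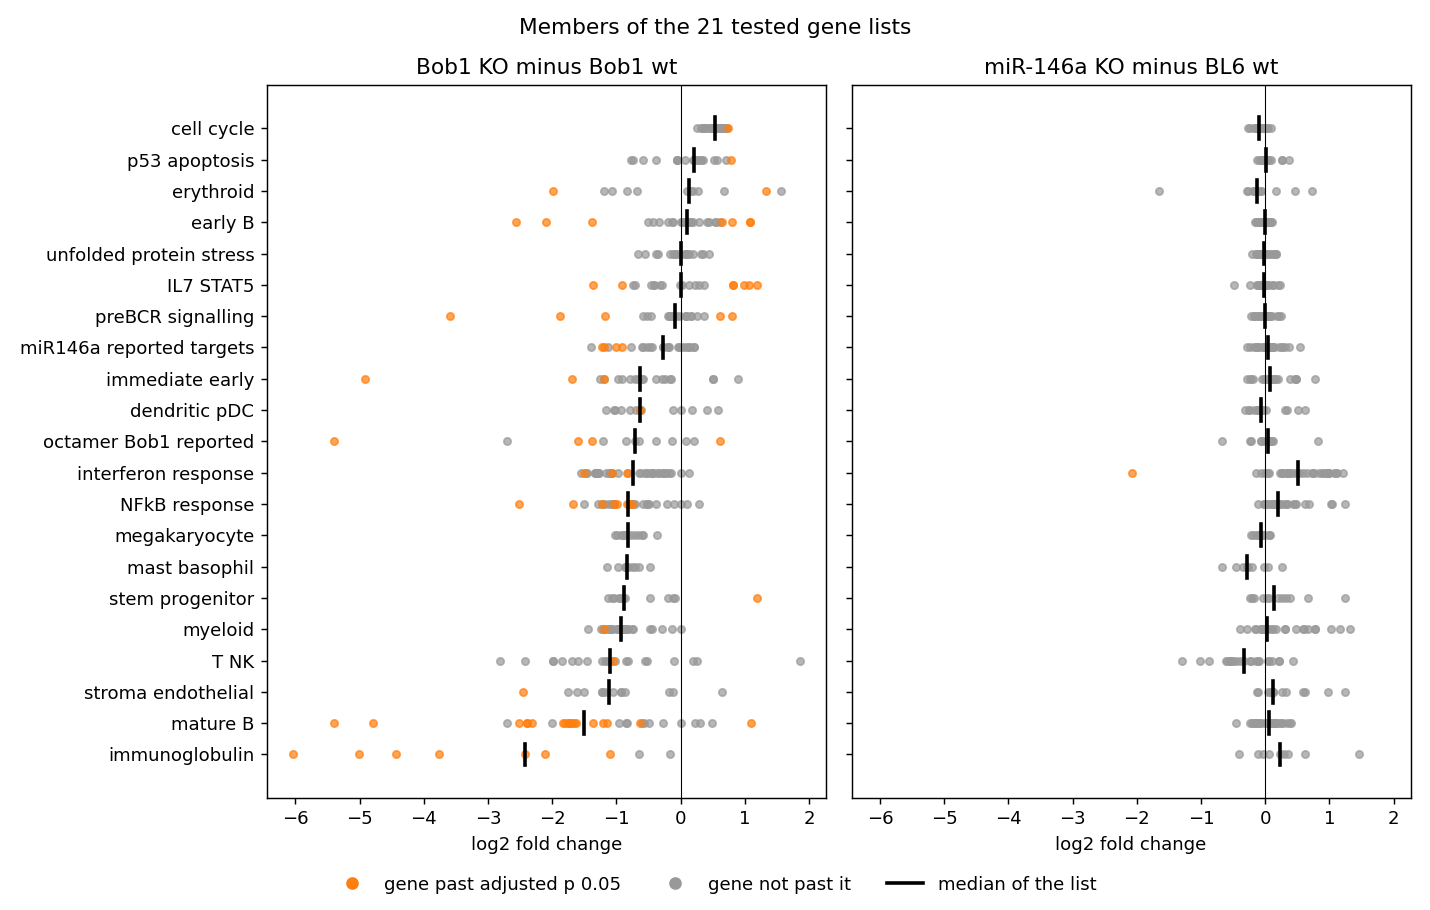
Log2 fold changes of the members of the 21 tested lists in the Bob1 and miR-146a knockout comparisons, with orange points past an adjusted p of 0.05, grey points not past it, and a black bar at the list median. In the Bob1 comparison the immunoglobulin (median -2.42) and mature B cell (-1.50) lists lie lowest and the cell cycle list (0.54) highest, while in the miR-146a comparison the medians lie between -0.33 (T and NK) and 0.52 (interferon).

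The miR-146a knockout cultures differed from BL6 wild-type cultures in few transcripts. Hmmr, which encodes a hyaluronan receptor of the mitotic spindle, fell 17.3-fold, from 2.48 ± 0.05 to -1.63 ± 0.25 (SD, n = 2 each; log2 fold change -4.11, SE 0.15, limma adjusted p = 0.000531), with -3.90 within slide 1 and -4.32 within slide 2. The other Hmmr probe had 0.05, so the probes of this gene disagree. Pttg1, which encodes securin, rose 3.36-fold (1.75, SE 0.13, adjusted p = 0.0101, and 1.79 and 1.71 within the slides). Leap2, an antimicrobial peptide gene, and Atp8b3, a phospholipid flippase gene, were well above background only in the knockout and rose at least 3.28-fold (0.00146) and 4.2-fold (0.000531). The GTPase gene Ifi47, which interferon induces, fell 4.22-fold (-2.08, adjusted p = 0.0418). Tmod4 rose 4.67-fold (0.0182), Lyrm7 2.16-fold (0.0465), Sprr4 at least 4.27-fold (0.0331) and Lrmda 19.0-fold (0.0418). Jakmip3 and Sall3 were well above background only in BL6 wild-type cultures and fell at least 4.66-fold (0.00141) and 1.83-fold (0.00366).

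In all, 18 features were called, of which 12 rose and 6 fell, with 502 at an unadjusted p under 0.05. That is less than a share of 0.05 of the 17493 tested, so this count gives no sign of a wider signal. It cannot exclude one, since the count depended on the fit and was 767 with the replicate letter as a block. The calls also included Gm16867, which rose at least 2.42-fold (limma adjusted p = 0.00171), and 5 probes without a symbol, all chosen after their values were seen. Of these, A_52_P762901 rose at least 10.9-fold (0.000335), A_52_P802990 at least 5.35-fold (0.00149), A_52_P877058 at least 2.12-fold (0.0166) and A_51_P286426 4.41-fold (0.0166), and A_52_P379037 fell at least 2.03-fold (0.00766). Each of the 18 had the same sign within both slides, and with the slide as a block 12 were called (7 up, 5 down). The calls of Ifi47 (0.139), Lyrm7 (0.146), Lrmda (0.0781), Tmod4 (0.0781), Sprr4 (0.0733) and Pttg1 (0.0507) were lost in it. For 11 of the 18 (7 that rose and 4 that fell) the dimmer side was not well above background. The number of calls was 11 without miR-146a knockout replicate B or without either Bob1 wild-type array, and 12 without miR-146a knockout replicate A. The split of rises and falls turned without a BL6 wild-type array, with 24 calls (6 up, 18 down) without replicate A and 15 (6 up, 9 down) without replicate B. In the deposited table limma called only Hmmr, with 934 features at p under 0.05.

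Single arrays decided 10 of the 18 calls. Ifi47 and Lyrm7 were lost without each of the 8 arrays (0.0554 to 0.255 and 0.11 to 0.352). Pttg1 was lost without BL6 wild-type replicate A (0.0557) or B (0.0913) or miR-146a knockout replicate A (0.0806) or B (0.127). Tmod4 (0.0746 to 0.192), Lrmda (0.0557 to 0.276) and A_51_P286426 (0.0746 to 0.111) were lost without any wild-type or miR-146a knockout array, and A_52_P877058 without any wild-type array (0.0746 to 0.115). Sprr4 was lost without all but miR-146a knockout replicate B (0.0505 to 0.216), and A_52_P379037 without miR-146a knockout replicate A (0.0739) or B (0.0675). Against all 4 wild-type arrays as the control, Jakmip3, Sall3, Lrmda, A_52_P379037 and A_51_P286426 had an adjusted p of 1.

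Of the 18 called features 17 had a position, and 5 of these lay on chromosome 11, which holds 8.4% of the tested features with a position. They were Hmmr (mm9 40514892 to 40514951), Pttg1 (43233801 to 43233860), Ifi47 (48910173 to 48910232), Leap2 (53235798 to 53235857) and Lyrm7 (54652034 to 54652093), so they spanned 14.1 Mb. In the gene table of assembly GRCm38.p6, the miR-146a gene Mir146 lies between Gm51418 and Gm5782, and Pttg1 is the gene after Gm5782. Of these 5 genes 3 rose and 2 fell. Hmmr and Leap2 kept their call without each array in turn, while Pttg1, Ifi47 and Lyrm7 were lost as given above (for example 0.127, 0.255 and 0.304 without miR-146a knockout replicate B).

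**Figure D3:**
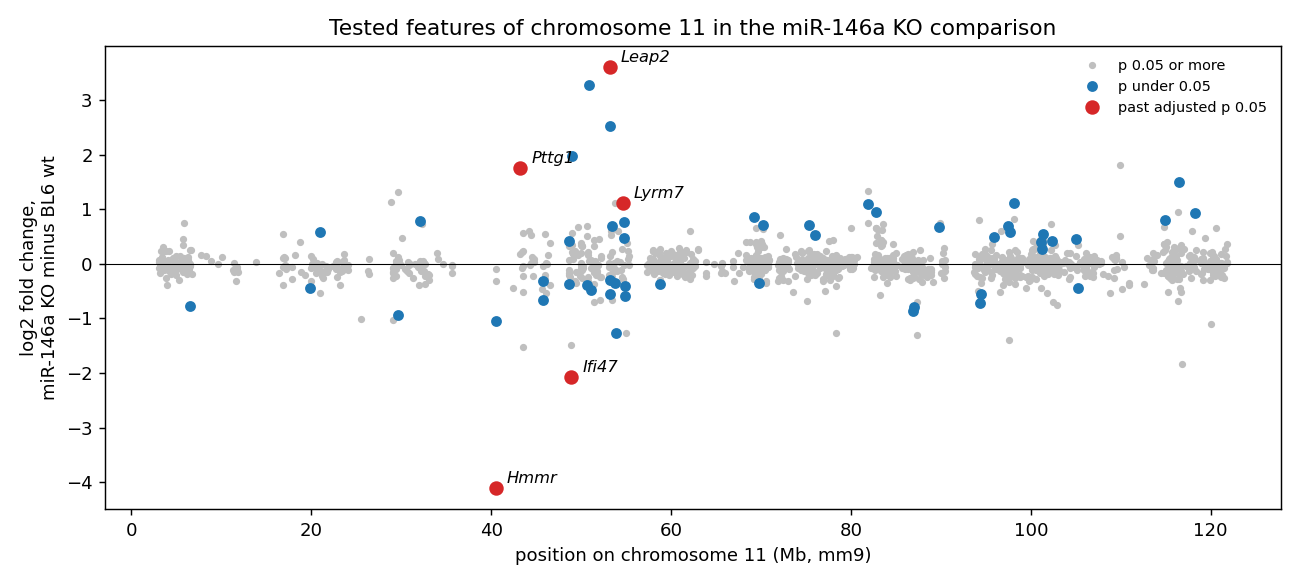
Log2 fold changes of miR-146a knockout against BL6 wild-type for the tested features along chromosome 11 (mm9 position in Mb), with the called genes in red and named and other features at p under 0.05 in blue. The 5 called genes lie within 14.1 Mb, with Hmmr lowest at -4.11. Leap2 is drawn highest of the 5 at its fitted value, but its rise has only a bound, so that rank is not established.

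Genes of the inflammatory lists shifted upward by small amounts without calls of single members that rose. Of 38 interferon response genes limma called 0 as risen (2 at p under 0.05), and the only called member, Ifi47, fell, against the direction of the list. The list median was 0.52 (0.10 within slide 1 and 0.93 within slide 2; camera adjusted p = 1.97e-12, and adjusted p = 0.969 with an estimated correlation; 5.02e-13 with the slide as a block), and the call was lost without BL6 wild-type replicate B (0.0753). Of 30 NF-kB response genes limma called 0, also over the list alone (4 higher at p under 0.05), with a median of 0.19 (0.13 and 0.34 within the slides; adjusted p = 8.95e-08, and adjusted p = 0.839 with an estimated correlation; 1.46e-07 with the block). Bcl2a1b and the kinase gene Ikbke had 1.04 and 0.69 (adjusted p = 1 for both). Of 29 myeloid markers limma called 0, also over the list alone (2 higher at p under 0.05), with a median of 0.03 and a mean of 0.25 (medians -0.22 and 0.35 within the slides; adjusted p = 0.00901, and adjusted p = 0.969 with an estimated correlation; 0.0134 with the block). C1qb and Cd14 had 1.31 and 0.78 (adjusted p = 1 for both). The myeloid call was lost without BL6 wild-type replicate B (0.699, with the direction turned down) or miR-146a knockout replicate B (0.0854), and against all 4 wild-type arrays (0.0634). Of 9 immunoglobulin genes limma called 0 (1 higher at p under 0.05), with 1 rise adjusted over the list alone and a median of 0.24 (0.09 and 0.50 within the slides; adjusted p = 0.0422, and adjusted p = 0.969 with an estimated correlation; 0.0628 with the block). That call was lost without BL6 wild-type replicate A (0.0504) or B (0.207) or miR-146a knockout replicate A (0.513), against all 4 wild-type arrays (0.132), with no filter on dim probes (0.0546) and with the mean of a gene's probes (0.103), and Jchain had 1.46 (adjusted p = 0.487). The interferon and myeloid lists were also called upward by camera in Bob1 wild-type over BL6 wild-type cultures. Those calls were lost with an estimated correlation (adjusted p = 0.986 for each) and with the slide as a block (0.278 and 0.854). By fry none of these lists was called (adjusted p = 0.967 for each).

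Genes reported as miR-146a targets did not shift as a group. Of 26 members limma called 0, also over the list alone (0 higher and 1 lower at p under 0.05), with a median of 0.05 (-0.05 and 0.14 within the slides) and a camera adjusted p of 0.346. The smallest p in the list were those of Smad4 (log2 fold change -0.29, SE 0.11, adjusted p = 1) and Relb (0.31, SE 0.15, adjusted p = 1). Nnt had -0.87 (adjusted p = 0.187, with -1 and -0.75 within the slides), and its unadjusted p was under 0.05. Its probes moved alike, by -0.81, -0.73 and -0.87. In the Bob1 comparison it had 0.41 without a call, and in the difference of the effects it was called upward (1.28).

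The other 16 lists were not called by camera. Limma called 0 members in each, also over the list alone. At p under 0.05 there were 2 dendritic, 1 immediate early, 1 octamer, 1 stem cell and 1 stromal member higher, 1 mature B cell member lower, and 0 in the rest apart from the miR-146a targets. The medians were 0.002 for early B cell genes (adjusted p = 0.884, test up, mean -0.02), 0.003 for pre-B cell receptor signalling (0.815, test up, mean -0.005), 0.05 for mature B cell (0.279), 0.04 for octamer (0.815), -0.02 for IL-7 (0.884), -0.10 for cell cycle (0.111), 0.01 for p53 (0.412), -0.03 for unfolded protein stress (0.815, test up) and 0.07 for immediate early genes (0.154). Among the markers of other cells they were -0.12 for erythroid (0.815), -0.33 for T and NK (0.28), -0.07 for dendritic (0.224, test up), -0.28 for mast (0.812), -0.06 for megakaryocyte (0.892), 0.12 for stromal (0.111) and 0.13 for stem cell markers (0.154). The values within the slides disagreed on several of these, with -1.20 and 0.48 for T and NK, -1.35 and 0.78 for mast, -0.87 and 0.65 for megakaryocyte and 0.99 and -0.24 for stromal markers. Each of them sets a female array against a male array, so slide, sex and single array cannot be told apart in this. Leaving out 1 array gave calls in several of them, some in opposite directions. Without BL6 wild-type replicate B, camera called T and NK (7.4e-06), mast (5.16e-05) and megakaryocyte markers (0.00146) down. Without BL6 wild-type replicate A it called mast (0.0285), megakaryocyte (0.0249), dendritic (0.00137) and stem cell markers (0.00116) up and cell cycle genes down (0.00337). Without miR-146a knockout replicate A it called T and NK markers down (0.00924) and stromal markers up (0.00393, and 0.0499 without either Bob1 knockout array). Without miR-146a knockout replicate B it called mature B cell genes (0.00227), dendritic (0.00285) and stem cell markers (0.0415) up and cell cycle genes down (0.00271). With the replicate letter as a block, camera called T and NK markers (0.00782) and cell cycle genes (0.0491) down and stromal (0.0442) and stem cell markers (0.0491) up.

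The wild-type groups, which come from separate sets of mice, were compared for the background between such sets. Limma called 8 features (3 higher and 5 lower in Bob1 wild-type), with 381 at p under 0.05, less than a share of 0.05 of those tested. Tmem254a was 6.41-fold higher in Bob1 wild-type (3.31 ± 0.15 against 0.64 ± 0.03, SD, n = 2 each; adjusted p = 0.00262, and 0.0315 with the slide as a block). Jakmip3 and Sall3, which were well above background only in BL6 wild-type among all 4 groups, were at least 5.31- and 2.08-fold lower (0.00213 and 0.00361). Another 4 calls were probes without a symbol, chosen after their values were seen, of which A_52_P379037 showed the pattern of Jakmip3 (at least 2.32-fold lower, 0.00579), A_51_P139641 was at least 27.6-fold lower (0.000311), and A_52_P811047 and A_52_P2609 were at least 8.31-fold (0.00262) and 4.62-fold higher (0.0376). Lrmda, which rose in the miR-146a comparison, lay at -0.32 in Bob1 wild-type against -4.30 in BL6 wild-type (log2 fold change 3.98, adjusted p = 0.117). Nnt had 0.02 between the wild-type groups, a value near 0 that was -0.04 without Bob1 wild-type replicate B. The number of calls was 35 without Bob1 wild-type replicate A, and 22 and 12 without BL6 wild-type replicate A and B, A_52_P2609 lost its call without any wild-type array (0.0725 to 0.326) or either miR-146a knockout array (0.15), and A_52_P379037 without Bob1 wild-type replicate B (0.0507). With the slide as a block 6 were called, and A_52_P379037 (0.0812) and A_52_P2609 (0.385) were lost, and with the replicate letter and the slide together 0 were called (427 at p under 0.05). Camera called stromal (median 0.91, adjusted p = 0.000128), interferon (0.22, 0.000582) and myeloid lists (0.15, 0.0497) upward in Bob1 wild-type, with adjusted p = 0.986 for each with an estimated correlation and 0.057, 0.278 and 0.854 with the slide as a block.

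The effects of the knockouts were set against each other by testing their difference. Limma called 361 features, 126 higher and 235 lower in the Bob1 effect than in the miR-146a effect, with 3830 at p under 0.05. The genes with the lowest fitted differences included Iglv1 (-6.10, SE 0.50, adjusted p = 0.00366), Ly6d (-5.92, 0.00336), Prm1 (-5.85, 0.00229) and Jchain (-5.23, 0.00229), and among the highest was Hmmr (4.83, 0.000562). The other Hmmr probe had 0.57 in the Bob1 and 0.05 in the miR-146a comparison, so the difference for Hmmr depends on the probe. Egr3 (0.00373), which differed downward, and ccdc198 (0.0263), Ccl21a (0.000548) and Edil3 (0.000798), which differed upward, were not well above background in one of the Bob1 groups, so the size of their difference is not given. Jakmip3 was called upward (0.00146) by its level in BL6 wild-type alone, as it was not well above background in the other groups. The call of ccdc198 was lost without any BL6 wild-type, miR-146a knockout or Bob1 knockout array (0.0534 to 0.103). Of 32 mature B cell genes 14 differed downward (list median -1.58, camera adjusted p = 1.25e-14, and adjusted p = 0.193 with an estimated correlation), as did 4 of 9 immunoglobulin genes (-3.03, 9.97e-10, and 0.193) and 3 of 30 NF-kB genes (-1.12, 7.7e-14, and 0.193). The difference was also downward for the interferon list (-1.28, 1.66e-13, and 0.381) and upward for cell cycle genes (0.66, 1.35e-07, and 0.403). With the slide as a block 70 features were called, with the replicate letter as a block 593, and with the slide Egr3 (0.0504) and ccdc198 (0.188) lost the call. The count was 158 and 164 without Bob1 wild-type replicate A and B, 218 and 127 without BL6 wild-type replicate A and B, and 131 and 136 without miR-146a knockout replicate A and B.

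Across the 17493 features the 2 effects, which share no arrays, had a Pearson r of -0.18 and a Spearman rho of -0.24, and genes are not independent replicates. The Pearson r was 0.02 without BL6 wild-type replicate B, -0.29 without BL6 wild-type replicate A and -0.09 with the slide as a block. Hmmr and A_52_P762901 were called in both comparisons, where independent lists would share 1.23. For Hmmr this holds for the tested probe, as the other had 0.57 in the Bob1 and 0.05 in the miR-146a comparison. Hmmr rose 1.64-fold in Bob1 knockout (adjusted p = 0.0435, and 0.257 with the slide as a block), against its fall in miR-146a knockout, and the former call was lost without each of the 8 arrays (0.0535 to 0.181). The probe A_52_P762901 was not well above background in either Bob1 group, so its Bob1 value carries no fold, and its Bob1 call was also lost without each of the 8 arrays (0.0605 to 0.203).

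**Figure D4:**
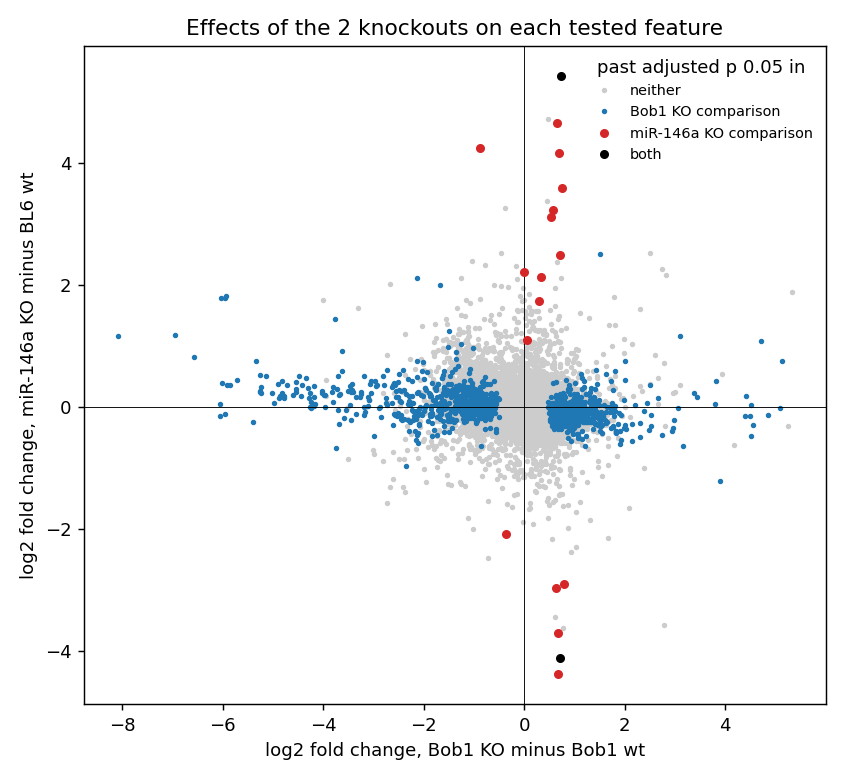
Log2 fold change of miR-146a knockout against BL6 wild-type plotted over that of Bob1 knockout against Bob1 wild-type for each tested feature, with grey for features called in neither comparison, blue for Bob1 only, red for miR-146a only and black for both. The 1198 Bob1 calls spread along the Bob1 axis, and only Hmmr and A_52_P762901 are black.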

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

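Both normexp settings without spots under their local background, and the count of immunoglobulin features by description, were chosen after seeing the data. All other settings were fixed before. Limits are the small number of arrays, the slides that coincide with the Bob1 genotypes and, for dim genes, the signal over background, since 130 of the 1198 Bob1 calls and 11 of the 18 miR-146a calls have a side that was not well above background. The control mice of the miR-146a comparison are labelled C57BL/6Ncrl. Any difference in substrain or origin from the knockout mice would coincide with genotype there. The 18 calls therefore cannot be assigned to the loss of miR-146a alone. The 1198 Bob1, 18 miR-146a, 8 wild-type and 361 difference calls stayed within 1.5 times under quantile normalization (1209, 18, 7 and 353), with every probe tested (1289, 19, 9 and 355) and with the mean of a gene's probes (1289, 19, 9 and 382). Normexp with the 75th percentile called 0 features in each of the 4 contrasts (123, 1, 5 and 65 at p under 0.05). On 4 arrays, its fitted background mean was negative (-2127 to -250) because 2 to 6 spots had a local background far above their signal, against 8.04 to 10.52 on the others. Without those spots the fitted means were 9.04 to 9.72 and the counts 3557, 14, 6 and 846. With quantile normalization in addition, the miR-146a and wild-type counts were 3 and 2 by normexp, and 8 and 3 without those spots. In the following, the cause was not tested unless it is named. With no filter on dim probes, the Bob1, miR-146a and difference counts were 558, 9 and 127. With only probes above background on all 8 arrays, which removes one-sided calls, the miR-146a and wild-type counts were 6 and 1. A trended and robust prior gave 4 wild-type and 608 difference calls, and the deposited table gave 1 miR-146a call, 2 wild-type and 159 difference calls. With only the arrays of a comparison, which leaves fewer degrees of freedom, the counts were 307 for Bob1, 11 for miR-146a and 5 for the wild types. Against all 4 wild-type arrays 2822 Bob1 features were called. At an adjusted p of 0.10 the Bob1 and difference counts were 2691 and 976, and with a 2-fold minimum on fitted folds 656 Bob1 calls were left.

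The slide as a block gave 122 Bob1 and 70 difference calls, since the slide estimate rests on 4 arrays. Replicate letters coincide with sex in every group, a factor that the main fit leaves out. The A minus B deviations of the groups correlated at 0.07 to 0.377 (0.134 for the Bob1 and 0.218 for the miR-146a pair of groups), so part of the spread between replicates was shared. The replicate block gave 1867 Bob1 calls (1177 of them shared) and 593 difference calls. With the replicate block and the slide together the counts were 133 for Bob1, 11 for miR-146a, 0 for the wild types (427 at p under 0.05) and 82 for the difference. The replicate block also raised the miR-146a list calls from 4 to 8, adding T and NK markers (0.00782) and cell cycle genes (0.0491) downward and stromal (0.0442) and stem cell markers (0.0491) upward.

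The correlation of both effects across genes (-0.179) was 0.254 with normexp, so its sign turned, and -0.085 without a filter and -0.089 with the slide block, with or without the replicate block. Against all 4 wild-type arrays it was 0.009, but the effects then share their controls, which raises a correlation, so that value does not bear on the sign. Of the gene lists, camera with an estimated correlation called 0 in either knockout comparison (4 and 1 at p under 0.05), and fry called 7 for Bob1 and 0 for miR-146a (0 at p under 0.05). The miR-146a lists called were 15 with normexp and 2 against all 4 wild-type arrays, in place of 4.

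Leaving out each array in turn leaves a group of 1 array that is assumed to vary like the others. The counts then ranged from 346 to 830 for Bob1, 11 to 24 for miR-146a, 7 to 35 for the wild types and 127 to 272 for the difference, the correlation from -0.285 to 0.024, and the lists called from 12 to 16 for Bob1 and 4 to 8 for miR-146a. The lowest values were those without Bob1 wild-type replicate A (346 calls and 12 lists) and, for the correlation, without BL6 wild-type replicate A (-0.285).

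Few named genes changed sign, and those lay near 0 or below background. In the Bob1 comparison, Ermap was 0.125 under normexp without spots under their background, and A_52_P762901 was -0.182 and -0.037 under both normexp settings, -0.005 in the deposited table and -0.074 under normexp without spots under their background with quantile normalization. In the miR-146a comparison, Smad4 was 0.023 under normexp. Pou2af1 there was 0.017 under quantile normalization, 0.389 and 0.094 under the normexp settings, 0.094 in the deposited table, 0.003 against all 4 wild-type arrays, 0.056 and 0.094 under normexp without spots under their background, and -0.185 to 0.106 without each array in turn. The log2 fold change of Nnt, Bob1 wt vs BL6 wt, was -0.063 to 0.11 without each array in turn. Of the 73 genes with a Bob1 value, 27 kept their side of the threshold with the slide block, 53 in the deposited table, 68 under quantile normalization and 8 under normexp. Of the 28 with a miR-146a value, 22 did so with the slide block and 10 in the deposited table. Planned tests of miR-146a seed matches and octamer promoters were not run, for want of a genome sequence.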

Other observations

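All tests weighed here were chosen only after the results they concern were seen. The immunoglobulin loss in Bob1 knockout cultures had a median log2 fold change of -3.71 for kappa features (47 of 55 fell) and -4.16 for lambda features (6 of 7), against -1.02 for heavy chain features (51 of 61). With unmeasured features at their bound these were -3.41, -4.16 and -0.99. The shares that fell were alike, and the difference between the classes was not tested. Of 11 pro-B genes, chosen after the result was seen, limma called 0. Their log2 fold changes were 0.53 for Vpreb1, 0.62 for Vpreb2, 0.45 for Igll1, 0.55 for Myb (adjusted p = 0.0614), 0.094 for Bst1, 0.057 for Cd93, 0.019 for Dntt, 0.015 for Lef1, -0.114 for Erg, -0.116 for Flt3 and -0.131 for Sox4, so 7 of the 11 lay at or below the median of all features (0.12).

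In the miR-146a comparison a pair of called features outside chromosome 11 also lay close together. Gm16867 (69984182) and the probe A_52_P762901 (70023335) lie on chromosome 14, were well above background only in miR-146a knockout cultures and rose. Nearby, A_51_P178377 had a log2 fold change of 2.52 (adjusted p = 0.0552) and Entpd4 0.96 (adjusted p = 0.24). These features were singled out after their values were seen, and no explanation was tested for them.

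The calls of the miR-146a comparison gathered on the part of chromosome 11 that holds the miR-146a gene. Within the interval between the outermost calls, 15 of 131 uncalled features (11.5%) had p under 0.05, against 405 of 15645 (2.6%) on other chromosomes (Fisher's exact test, two-sided p = 2.13e-06). Of 1870 windows of the same length elsewhere, moved in steps of 1 Mb and so overlapping, 0 reached that share. The highest, on chromosome 12, came close at 11.3%. Fisher's test treats neighbouring features as independent, and the calls themselves set the ends of the interval. Its upper end was set by Lyrm7, whose call was lost with the slide as a block and without each array in turn. These values therefore speak against chance placement only weakly. Of the 5 called genes there 2 fell, which argues only weakly against direct release from miR-146a as the explanation for all of them. The other probe of Hmmr, one of the 2, had 0.05. The call of Ifi47, the other gene that fell, was lost with the slide as a block and without each array in turn. For the 3 that rose direct release stays open, since seed matches were not searched. A candidate explanation in line with these values is a stretch of chromosome 11 that differs between the knockout and the BL6 wild-type mice, but a carried stretch of another strain's sequence and effects of the engineered allele on its neighbours cannot be told apart here.

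The largest pattern was the loss of mature B cell and immunoglobulin transcripts in Bob1 knockout cultures, with a median log2 fold change of -1.78 over 165 features (95% interval -2.49 to -1.52). The intervals in this paragraph are taken over features of the same arrays and treat them as independent. They do not measure the spread between cultures, and related features make them too narrow. An offset common to all arrays of a slide is argued against, because with the slide as a block a median of 101.9% of the log2 fold change was kept (quartiles 96.5% and 106.7%; median -1.84), although calls went from 132 to 42 as the median SE rose from 0.24 to 0.35. A slide or scan difference confined to the Bob1 arrays and the genotype cannot be told apart, since each genotype lay on a slide of its own. Whether fewer cells of other types contribute stays open. In the myeloid, T and NK, dendritic, mast and megakaryocyte lists, 78 markers with a level high enough to show the pattern's median fall had a median of -0.88 (-0.98 to -0.82). The intervals of the myeloid (-1.084 to -0.835) and megakaryocyte markers (-0.935 to -0.607) lay above that of the pattern. So did those of the dendritic (-1.028 to 0.183) and mast markers (-1.154 to -0.474). Only the interval of the T and NK markers, at -1.11 (-1.84 to -0.56), overlapped that of the pattern. Among them, Ccl5 and Lat (levels 2.71 and 2.02), chosen after their values were seen, had -1.17 and 0.19. A larger share of pro-B cells could also lower these transcripts, and stays open, with 11 pro-B genes at a median of 0.057 (-0.12 to 0.55) against 0.12 for all features, and 0.53 for Vpreb1, which lay at 7.92 in Bob1 wild-type cultures.

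Several calls rest on probes that were well above background in both arrays of a group and nowhere else. Spot artefacts shared by the arrays of a slide could produce them where both arrays lie on 1 slide, as in the Bob1 groups. For each pair of arrays, such probes were counted only if both arrays also lay more than 2 above every other array on the log2 scale. The Bob1 knockout pair held 18 probes with that step, against a median of 2.5 and at most 7 over 10 pairs of arrays from the same slide and different groups. Over 14 pairs that shared neither slide nor group the median was 3.5 and the highest count 10. The count of 18 argues against these artefacts as the whole cause there, for probes with that step. Probes with a smaller step were not counted. The Bob1 wild-type pair held 3, within the range of those pairs (1 to 7), so for it such artefacts and the genotype cannot be told apart by this count. The BL6 wild-type and miR-146a knockout groups have 1 array on each slide, so an artefact confined to 1 slide does not reach both arrays of such a group, and pairs of arrays from the same slide are no control for them. What sets probes such as Jakmip3 and Sall3 apart in BL6 wild-type was not tested.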
